A study of Mus musculus with 8 samples.

How the data were processed

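Total RNA from mouse bone-marrow-derived macrophages was labelled with biotin and hybridised to Affymetrix arrays, 8 in all, 1 for each combination of 4 strains with infection by L. major or none. Each sample pooled cells from 6 mice. The macrophages were grown with L-cell conditioned medium after a step that discarded the first adherent cells, which the submitters used to remove fibroblasts. They were exposed to the parasite or not for 4 hours, washed, and harvested 24 hours later. Whether the infected and the uninfected pool of a strain came from the same mice is not stated in the labels.

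The deposited table holds log2 expression values for 12488 probe sets, made by the authors with GCRMA per the submitters' processing notes, which adjusts the background by probe sequence, normalises between arrays and summarises probes into probe sets. Its version and settings are not given in the sources used here. Values ran from -0.73 to 13.66, which leaves the log2 scale as the one that fits an array scanner. Raw intensities and detection calls were not used here, so signal over background could be judged only by the expression filter.

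After 66 control probe sets were set aside, 12422 remained, of which 10833 were paired with 1 gene symbol, 396 with several and 1193 with none. Probe sets with several symbols or none were left out of the gene tests. Gene identifiers of 10817 of the 10833 were found in the gene table of assembly GRCm38.p6, used for chromosomes and gene order only. Each of 8251 genes was represented by its probe set of highest mean, and 3345 genes with a value above log2 5 on at least 2 of 8 arrays were tested.

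Linear models were fitted with limma 3.58.1 in R 4.3.3 with empirical Bayes moderation, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The infection effect had strain as a fixed term. Background and segment origin were fitted together with infection, with strain as a random block whose consensus correlation was -0.543. The interactions of infection with background and with segment origin were fitted on the 4 within-strain differences and left 1 residual degree of freedom. The infection effect within each background, on 4 arrays, was added after the data were examined. The strains are the only replication. For infection and the interactions, p-values measure how much the strains differ in their response. For background and segment origin, with 4 residual degrees of freedom, they rest mostly on such differences in response too. Only the fit with the arrays of a strain averaged rests on the spread between strains alone, and it too leaves 1 residual degree of freedom before moderation. Locations of genes called for segment origin were compared with all tested genes by a one-sided Fisher exact test on chromosomes 9 and 17.

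Fixed before the data were examined were 26 gene lists, including markers of other cells a marrow culture can hold. The 20 with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, and members were counted over all genes tested and adjusted over the list alone. With an estimated correlation camera takes p from the residual degrees of freedom of the fit. These were 3 for infection, 4 for background and segment origin, and 1 within each background and for infection by background. With 1 a list can hardly pass, so a failure there is no evidence against it. For background and segment origin the preset version used the t-values of the fit with the strain block. The version with an estimated correlation used a fit without it, so there the versions differ in more than the correlation.

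Named genes followed a rule also fixed before. For infection they were the 12 largest rises and 12 largest falls with the same sign in all 4 strains, and for background and segment origin the 10 and 10 largest past the threshold with the same sign in both strain comparisons and infection states. Where fewer passed, genes that did not pass followed in order of size and are given as values. The rule took the 5 genes of smallest p for each interaction and up to 4 members of each list. H2-Ea, Fli1, Arg1, Nos2, Il12b, Tnf, Il10, Il1b and Tgfb1 were always included. The rule was applied likewise to the added fits. Timp1, Cadm1, and single values of Cxcl1, Cxcl2, Mt1, Mt2 and Iigp1 in the BALB/c background were named after their values were seen.

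The pipeline was tested on simulated data with 200 changed genes among 3345, with a single draw for each fit. The simulated strains did not differ from each other in their response to infection beyond noise. In the real data such differences enter the error of the infection, background and segment fits, so the recovered shares do not give their power there. For differences of log2 1, 2 and 4 the infection fit recovered 80.6%, 89.6% and 97% (4.8% of calls false), and the background fit 80.6%, 98.5% and 100% (17.3% false). The segment fit recovered 94%, 98.5% and 100% (14.1% false). Without the strain block 5.6% of background and 6% of segment calls were false, and with the arrays of a strain averaged 0.7% and 2%. In the simulation the blocked background and segment fits had strain correlations of -0.3 and -0.318, against -0.543 on the real data. False shares also depend on the number and size of planted changes, so they do not carry over to the real calls. The infection-by-background fit recovered 0%, 0% and 56.1%, the infection-by-segment fit 0% at each size, and the fit within the C57BL/6 background 4.5%, 58.2% and 84.8%.

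Alternatives covered the expression filter (none, or log2 7), testing every probe set, quantile normalisation again, shifting arrays to the same median, an intensity trend, other strain terms, leaving out each strain, an estimated correlation for lists, and the mean of all probe sets of a gene. Fits without the uninfected BALB/c array, with an infection-by-background term, and of each interaction alone without each strain were added after the data were examined. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.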

Results

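Gene expression was measured on 8 Affymetrix arrays hybridised with RNA from mouse bone-marrow-derived macrophages, cultured with or without the parasite Leishmania major. The cells came from 4 strains, and each strain gave 1 infected and 1 uninfected array, each from a pool of 6 mice. BALB/c mice are known to be susceptible to this parasite and C57BL/6 mice to be resistant, and lmr1 and lmr2 are resistance loci on chromosomes 17 and 9. C.B6-(lmr1, lmr2) is a congenic strain with C57BL/6 segments at these loci on the BALB/c background, and B6.c-(lmr1, lmr2) carries BALB/c segments on the C57BL/6 background. The design therefore crosses infection, background and segment origin, with no replicate array in any of the 8 combinations, and the number of arrays limits the precision of every value. Values are the deposited log2 expression values, and the errors given are standard errors of the fit. They rest on how the strains differ in their response, and for background and segment origin only in small part on the spread between strains.

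H2-Ea, an MHC class II gene on chromosome 17 that is known to be silent in C57BL/6 mice, separated the arrays by segment origin. Its log2 value was 7.78 on the infected and 7.45 on the uninfected BALB/c array, and 6.32 and 7.35 in B6.c-(lmr1, lmr2). It was 1.73 and 1.98 in C.B6-(lmr1, lmr2), and 1.85 and 1.77 in C57BL/6. Between 29.3% and 30.7% of probe sets lay above log2 5 on each array. The mean of 9 hybridisation spike-in probe sets, which no genotype changes, was 7.59 ± 0.14 (SD, n = 4 arrays) for the C57BL/6 background and 6.44 ± 0.27 (SD, n = 4) for the BALB/c background, a difference of 1.15 (two-sided exact permutation p = 0.0286, the smallest that 4 arrays against 4 can give). The labels name no hybridisation batch. The 3′ minus 5′ log2 difference of the actin control, a measure of RNA degradation, was 2.09 on the uninfected BALB/c array and between 0.90 and 1.42 on the other 7. It too separated the backgrounds, with means of 1.48 ± 0.42 (SD, n = 4) for BALB/c and 0.92 ± 0.02 (SD, n = 4) for C57BL/6 (difference -0.56, two-sided exact permutation p = 0.0286). Without the uninfected BALB/c array the difference was -0.36. The Gapdh 3′ minus 5′ difference, a second such control, did not separate the backgrounds. Its mean differed by -0.23 (two-sided exact permutation p = 0.4286), and by -0.01 without the uninfected BALB/c array (p = 0.8286).

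The first comparison asked which transcripts changed with the parasite across the 4 strains. Genes with the same direction in 4 of 4 strains included Saa3, an acute-phase protein, with a mean infected minus uninfected log2 difference of 3.39 ± 0.96 (SE, n = 4 strains), and the neutrophil chemokine Cxcl1, with 2.57 ± 0.52. Fabp5, a fatty acid binding protein, stood at 1.51, haptoglobin (Hp) at 1.48, Pdia6 at 1.03, Mmp8 at 0.99, Ly9 and Slc31a1 at 0.98, Cotl1 at 0.96, Clcn7 at 0.92, Rhog at 0.88 and the chemokine receptor Ccr1 at 0.87. Values on the other side were Hpgd, which degrades prostaglandins, at -3.24 ± 1.18, smooth muscle actin Acta2 at -2.33 ± 0.35, Gm4788 at -2.00, Ccn2 at -1.95, the collagens Col4a1 at -1.80 and Col5a2 at -1.44, Tle1 at -1.79, AU020206 at -1.54, Cd5l at -1.42, Ank at -1.37, Tagln at -1.22 and Nop56 at -1.14. With the mean of all its probe sets Nop56 stood at -0.62. None of these genes passed the test. With limma, 0 of 3345 genes passed an adjusted p of 0.05 (smallest adjusted p = 0.51), and 270 had an unadjusted p under 0.05. A count without a test found 23 genes with a mean difference of at least 1 and the same sign in 4 strains, 5 higher and 18 lower, and this count was 194 without C.B6-(lmr1, lmr2) and 62 without BALB/c. The sign was the same in all 4 strains for 574 genes, or 17.2%, against 19.3% if the BALB/c-background pairs were independent of each other and of the C57BL/6-background pairs, which shared a sign for 77.8% of genes.

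Of the 20 gene lists tested under infection over the 4 strains, camera called 9 as higher (adjusted p from 5.24e-05 to 0.0266) and the cell cycle list as lower (0.000148), and none held, each of the 10 having adjusted p = 0.565 with an estimated correlation. The 9 lists were cytokines and chemokines, type I interferon-stimulated genes, interferon-gamma-inducible genes, feedback regulators of NF-kB and MAPK signalling, hypoxia and glycolysis, lysosome, pattern recognition receptors, MHC genes and macrophage identity. All 9 tested cytokines and chemokines had positive mean differences (median log2 1.98), as did all 12 type I interferon-stimulated genes (median 1.25) and all 14 feedback regulators. All 15 cell cycle genes had negative values (median -1.38). Single members did not pass over all genes, and adjusted over the list alone 1 cytokine gene and 1 arginine and polyamine gene were higher and 2 fibroblast genes lower.

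The strain pairs differed in how many genes moved. At least 2-fold differences between the infected and the uninfected array numbered 429 in C57BL/6 (187 higher, 242 lower) and 470 in B6.c-(lmr1, lmr2) (154 higher, 316 lower), against 141 in BALB/c (78 higher, 63 lower) and 81 in C.B6-(lmr1, lmr2) (41 higher, 40 lower). Across genes, which are not independent replicates, the differences of C57BL/6 and B6.c-(lmr1, lmr2) correlated with Pearson's r = 0.892 and Spearman's rho = 0.742. Of the 6 correlations between strains, those of BALB/c were 0.215 with C57BL/6 and 0.13 with B6.c-(lmr1, lmr2). The C.B6-(lmr1, lmr2) pair gave -0.413 and -0.406 with these strains and -0.089 with BALB/c. The infection effect was therefore also fitted within each background, a step added after the data were examined.

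**Figure D1:**
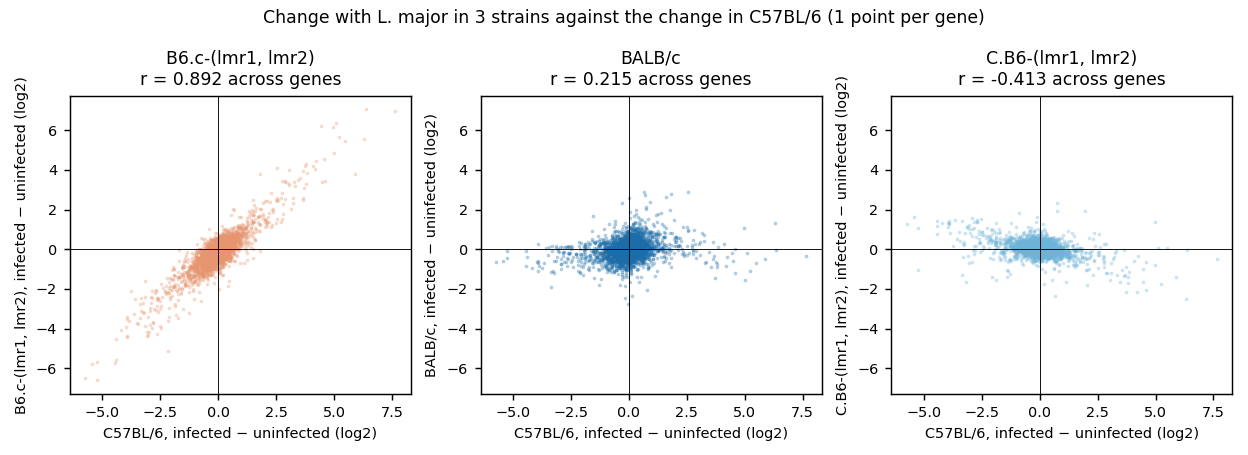
Infected minus uninfected log2 difference of each tested gene (1 point per gene, 3345 genes) in B6.c-(lmr1, lmr2), BALB/c and C.B6-(lmr1, lmr2), against the same difference in C57BL/6, from 1 infected and 1 uninfected array per strain. The points of B6.c-(lmr1, lmr2) follow a rising line (r = 0.892), those of BALB/c lie close to the horizontal axis (r = 0.215), and those of C.B6-(lmr1, lmr2) tilt the other way (r = -0.413).

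Within the C57BL/6 background, single genes differed strongly between infected and uninfected macrophages in both strains. Acod1, which makes the antimicrobial metabolite itaconate, rose by log2 7.31 ± 0.21 (SE, n = 2 strain pairs, adjusted p = 1.44e-05), from a mean log2 value of 2.85 to 10.16, and the scavenger receptor Marco rose by 6.71, from 1.98. The cytokine Il1b rose by 5.94, the chemokines Ccl5, Ccl2 and Ccl7 by 5.73, 5.32 and 4.33, Saa3 by 5.57, the interleukin-1 receptor antagonist Il1rn by 5.45, the formyl peptide receptor Fpr2 by 5.43, ceruloplasmin (Cp) by 4.92, the guanylate-binding protein Gbp2 by 4.85 and Ms4a4c by 4.55. Among genes that went the other way, Stmn1 (log2 -6.11), the prostaglandin-degrading Hpgd (-5.92), Nusap1 (-5.61), the proliferation marker Mki67 (-5.47), Pclaf (-5.09), the survivin gene Birc5 (-4.42 in C57BL/6 and -5.58 in B6.c-(lmr1, lmr2)), Kif23 (-4.47), topoisomerase Top2a (-4.17), Anln (-4.15), Cip2a (-4.14), the ribonucleotide reductase gene Rrm2 (-3.95) and Ect2 (-3.73) fell. In all, 782 genes passed, 297 higher and 485 lower, and 412 of them differed at least 2-fold. With each array shifted to the same median the excess of falls turned round, to 518 higher and 499 lower. For 22 of the 24 named genes, Ccl5 and Saa3 excepted, the lower side lay below the filter of log2 5, where background signal limits the size of a difference. With the mean of all probe sets of a gene, Stmn1, Nusap1, Mki67 and Pclaf stood at -2.99, -2.79, -2.62 and -2.84. The test rests on 2 strain pairs with 1 residual degree of freedom before moderation.

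The gene lists fixed before the data were examined were then tested in this background. At the preset correlation camera called 9 lists, the cell cycle list as lower and the others as higher (adjusted p from 5.46e-14 to 0.0333). With an estimated correlation none passed, the MHC list having adjusted p = 0.715 and the other 8 adjusted p = 0.59. That version rests on 1 residual degree of freedom and cannot decide. The cell cycle list, with an estimated correlation of -0.067, below the preset 0.01, went from camera p = 9.14e-14 to 0.0793. All 9 tested inflammatory cytokines and chemokines rose, over all genes and adjusted over the list alone, as did all 12 type I interferon-stimulated genes by both counts, among them Usp18 (log2 3.97), Rsad2 (3.80), Ifit1 (3.55) and Irf7 (3.53). Of 17 interferon-gamma-inducible genes 9 rose, 10 adjusted over the list alone, including Gbp2, Gbp3 (3.92), Iigp1 (3.39) and Igtp (2.55), whereas the class II genes H2-Aa and H2-Ab1, at 0.35 and 0.60, did not pass and differed between the pairs, with 1.23 and 1.22 in C57BL/6 and -0.52 and -0.02 in B6.c-(lmr1, lmr2). Of 14 feedback regulators of NF-kB and MAPK signalling 8 rose, 11 adjusted over the list alone, with Socs3 at 2.78 and Ier3 at 1.85. Of 11 pattern recognition and uptake receptors 9 rose and 1 fell, 10 and 1 adjusted over the list alone. The Fc receptor Fcgr1 rose by 2.23 and Tlr6 by 1.56, and the mannose receptor Mrc1 fell (-1.70). Of 15 cell cycle and DNA replication genes 14 fell, 15 adjusted over the list alone, and the exception, Plk1, stood at -0.47. In smaller shares, 6 of 15 hypoxia and glycolysis genes rose, with 6 higher and 1 lower adjusted over the list alone, led by Pfkl (1.43) and hexokinase Hk2 (1.24). Of 12 MHC genes 4 rose by both counts, and of 13 macrophage identity genes 5 rose and 1 fell by both counts, with the transcription factors Cebpb at 1.24 and Cebpa at -1.93.

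Several metabolic groups were mixed and were not called by camera in this background. Of 13 NRF2 oxidative stress genes 3 rose and 7 fell, 3 and 8 adjusted over the list alone, with catalase (Cat) at -1.28 and Gstm1 at 1.10. Of 10 LXR target genes 4 rose and 2 fell, 5 and 2 adjusted over the list alone. Nr1h3, which encodes LXR alpha, rose by 2.54, and lipoprotein lipase (Lpl) fell (-2.19). Of 6 metal-handling genes 3 rose and 2 fell by both counts, with Hp at 2.70 and the metallothionein Mt1 at -1.88. Of 12 matrix remodelling genes 3 rose and 5 fell, 3 and 6 adjusted over the list alone, with Mmp14 at 3.10 and Mmp12 at -1.88. Of 16 lysosome and phagosome genes 2 rose and 1 fell by both counts, with Ctsz at 1.25 and Lipa at -1.64. Of 3 genes of alternative activation Fcgr2b (3.12) and Il4ra (2.04) rose and Mrc1 fell. Of 11 genes of the unfolded protein response 2 rose and 2 fell, 4 and 2 adjusted over the list alone, with Psat1 at -3.21. Of 6 heat shock genes Dnaja1 rose (0.85). With limma, 0 of 5 sterol genes and 0 of 4 arginine and polyamine genes passed, the latter 1 higher and 2 lower adjusted over the list alone. Among markers of other cells, the fibroblast genes Acta2 (-3.06) and Col1a1 (-1.01) fell (2 of 4 tested), the neutrophil genes Mmp8 and S100a8 rose by 1.64 and 1.32 (2 of 2), the dendritic cell gene Cd83 fell (-2.59, 1 of 2) and the lymphocyte gene Il7r fell (-2.39, 1 of 1). Of 2 osteoclast genes Acp5 rose by 1.32 and Nfatc1 fell (-1.30). No member of the mast cell list or the erythroid list passed the expression filter.

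**Figure D2:**
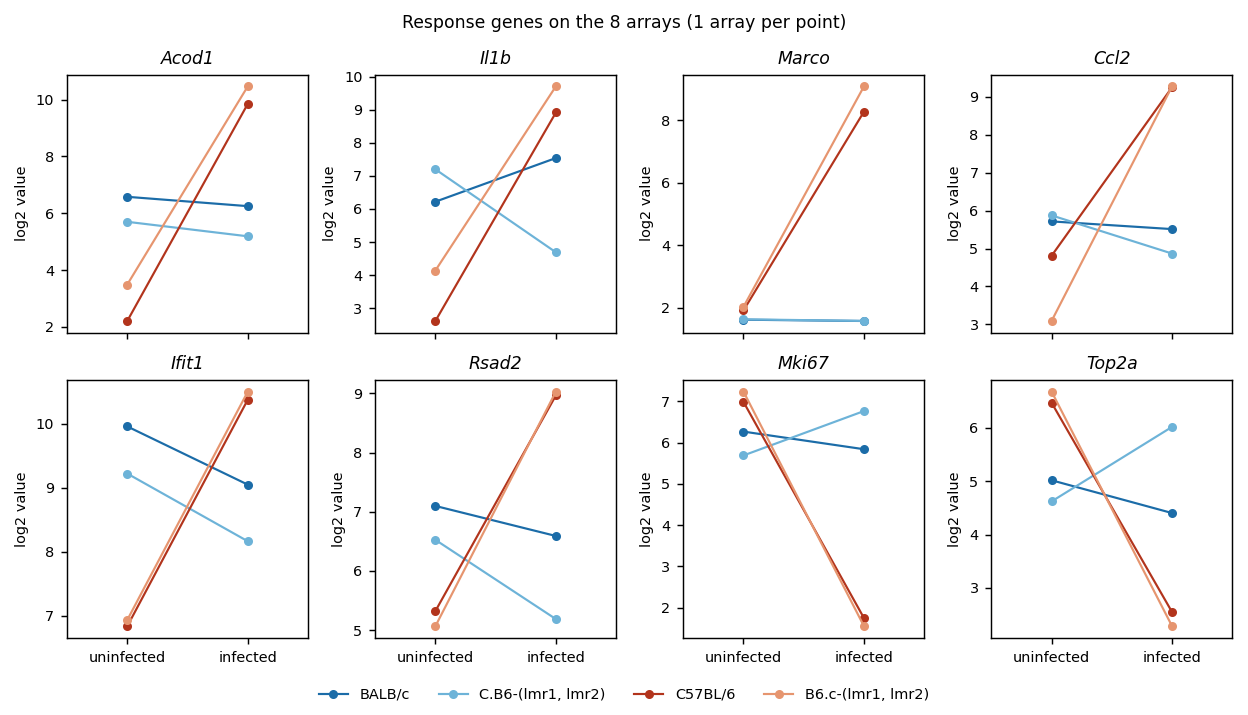
Log2 value of 8 response genes on the uninfected and the infected array of each strain, 1 array per point, with a line joining the arrays of a strain. Acod1, Il1b, Marco, Ccl2, Ifit1 and Rsad2 climb and Mki67 and Top2a drop in both strains of the C57BL/6 background. In the BALB/c background the lines are flatter, and Il1b runs from 7.20 uninfected to 4.69 infected in the congenic strain C.B6-(lmr1, lmr2).

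Within the BALB/c background no gene passed. The genes of smallest p were A530040E14Rik at log2 -1.51, the interferon-inducible GTPase gene Iigp1 at -1.81, Acta2 at -1.61, Ms4a4c at -1.64 and Saa3 at 1.21. The BALB/c pair had differences of 2.88 for Cxcl1, 1.99 for Cxcl2 and 1.32 for Il1b, and the C.B6-(lmr1, lmr2) pair had -2.51 for Il1b and -2.18 for Iigp1. At the preset correlation camera called the lists of type I interferon-stimulated (adjusted p = 4.94e-10) and interferon-gamma-inducible genes (4.07e-04) as lower. It called those of the cell cycle (0.0051) and lysosome (0.00227) as higher. With an estimated correlation none passed, each having adjusted p = 0.968, but that version rests on 1 residual degree of freedom and cannot decide. All 12 type I interferon-stimulated genes had negative values (median -0.71), 1 of 17 interferon-gamma-inducible genes was lower adjusted over the list alone, and 14 of 15 cell cycle values were positive (median 0.33). With limma, 0 of 3345 genes passed (smallest adjusted p = 0.998), and 74 had an unadjusted p under 0.05. The uninfected array of the BALB/c pair is the one with the largest actin 3′ minus 5′ difference.

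The response to the parasite differed between the backgrounds in its own test. The difference in response, C57BL/6 minus BALB/c background, was log2 7.74 for Acod1, 6.83 for Fpr2, 6.76 for Marco, 6.10 for Cp and -5.52 for Birc5 (adjusted p = 0.0116 for each, n = 4 within-strain differences). At the preset correlation camera called 8 lists, with adjusted p down to 1.82e-17. With an estimated correlation none passed, each having adjusted p = 0.774, but that version rests on 1 residual degree of freedom and cannot decide. Of the 12 type I interferon-stimulated genes 11 passed as higher, 12 adjusted over the list alone, with Trim30a at 1.74 the exception. Of 15 cell cycle genes 11 were lower, 13 adjusted over the list alone. Of 9 cytokines and chemokines 4 were higher, 9 adjusted over the list alone, and of 17 interferon-gamma-inducible genes 5 were higher, 9 adjusted over the list alone. In all, 119 genes passed, 54 with a higher and 65 with a lower response in the C57BL/6 background. The excess of lower responses turned round without a filter (44 genes, 23 higher and 21 lower) and with the log2 7 filter (143 genes, 75 higher and 68 lower). The BALB/c side of this test holds the uninfected BALB/c array, which has the largest actin 3′ minus 5′ difference (2.09), and the C.B6-(lmr1, lmr2) pair, whose response ran against the C57BL/6-background pairs. Without a segment term 293 genes passed, with the BALB/c strain also left out 381 and with C.B6-(lmr1, lmr2) left out 312, each with 12 of 12 type I interferon-stimulated genes higher, where the lone pair is assumed to vary like the others. Left out in the same way, C57BL/6 gave 55 genes and B6.c-(lmr1, lmr2) 21, with 5 and 3 of the 12. The design leaves 1 residual degree of freedom, and with an intensity trend in the variance limma called 0 genes, with 658 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0689.

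The second comparison asked which genes differ between the C57BL/6 and the BALB/c background averaged over infection states. Higher in the C57BL/6 background were Snhg6 (log2 3.90 ± 0.12, SE, n = 8 arrays), the kinesin gene Kif5b (3.85), the protease inhibitor gene Spint1 (3.85), Marco (3.73, with log2 values of at most 2.03 on all arrays except 8.28 and 9.09 on the infected C57BL/6-background arrays), Rap2b (2.71), Tspan32 (2.63), the interferon-inducible gene Ifi209 (2.46), Cd5l (2.28), pyruvate dehydrogenase kinase Pdk1 (2.27) and glutaredoxin Glrx (2.21). Lower were the interferon-inducible gene Ifi202b (log2 -7.97 ± 0.12, adjusted p = 2.47e-07), Pdxdc1 (-5.63), Plbd1 (-3.52), the guanylate-binding protein gene Gbp2b (-3.44), the chemokine receptor Ccr2 (-3.17), Gm4788 (-2.88), Cxcl14 (-2.64), Cd83 (-2.58), Cap1 (-2.55) and the arginase gene Arg2 (-2.51). By the rule that named them, these genes have the same direction in both strain comparisons and both infection states. These are values of the brightest probe set of a gene, and with the mean of all its probe sets Pdxdc1 stood at -0.51, Snhg6 at 1.97, Rap2b at 1.29, Cd83 at -1.44 and Arg2 at -1.26, each still past the threshold. The other probe sets of these genes therefore did not show a difference of that size. For Pdxdc1, with 3 probe sets, another must differ in the opposite direction. For 18 of the 20 genes, Glrx and Ccr2 excepted, the lower side lay below the filter of log2 5, where background signal limits the size. With limma 1612 genes passed, 752 higher and 860 lower, and 232 of them differed at least 2-fold. The excess of lower genes turned round with each array shifted to the same median (858 higher, 777 lower) and with the log2 7 filter (491 and 420). The planned fit estimated a correlation of -0.543 between the arrays of a strain, which shrinks standard errors, and on simulated data 17.3% of its background calls were false. The simulated fit had a correlation of -0.3, so that share does not carry over to the calls here. Without the strain block 667 genes passed, with the arrays of a strain averaged 1172 passed, and 659 passed in all 3 fits (324 higher, 335 lower). Marco and Ifi209 lost their calls without the block (adjusted p = 0.0916 and 0.0696). The spike-in difference of 1.15 and the actin 3′ minus 5′ difference of -0.56 (-0.36 without the uninfected BALB/c array) run along the same split of the arrays. The Gapdh 3′ minus 5′ difference did not separate the backgrounds (-0.23, or -0.01 without that array).

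**Figure D3:**
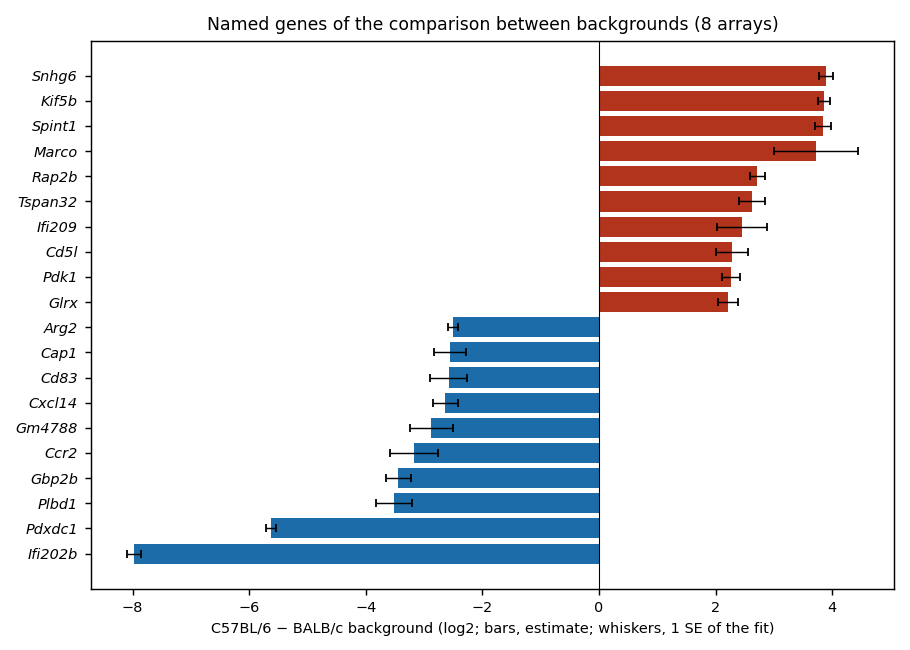
Estimated log2 difference between the C57BL/6 and the BALB/c background for the 20 named genes, from 8 arrays, with whiskers of 1 standard error. Values are those of the brightest probe set of each gene. The longest bar is Ifi202b at -7.97, and Marco and Ifi209, with standard errors of 0.72 and 0.43, have the widest whiskers.

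Camera called 5 lists as higher in the C57BL/6 background, those of hypoxia and glycolysis, heat shock, the unfolded protein response, NRF2 and sterol genes, and 1 as lower. None held with an estimated correlation, in a version that also left out the strain block. The actin 3′ minus 5′ difference (-0.56, or -0.36 without the uninfected BALB/c array) and the spike-in mean (1.15) differed along the same split. The Gapdh 3′ minus 5′ difference did not separate the backgrounds. Of 15 hypoxia and glycolysis genes 12 were higher and 1 was lower by both counts, over all genes and adjusted over the list alone, among them Pdk1, the glucose transporter Slc2a1 (1.48), Tpi1 (1.41) and Pgk1 (1.22), with Ndrg1 at -1.51 (camera adjusted p = 5.36e-07). Of 6 heat shock genes 5 were higher (0.0253), including Hspd1 (1.02) and Hsph1 (0.91), and of 11 unfolded protein response genes 6 were higher (0.0253), including Creld2 (0.91), Dnajb9 (0.79) and Xbp1 (0.79), with unchanged counts adjusted over the list alone. These 3 lists had adjusted p = 0.293 with an estimated correlation. Of 13 NRF2 genes 6 were higher and 1 lower, 9 and 2 adjusted over the list alone (0.0372, adjusted p = 0.565 with an estimated correlation), with heme oxygenase Hmox1 at 1.85 and Gclm at 1.29. Of 5 sterol genes 3 were higher, 5 adjusted over the list alone (0.0487, adjusted p = 0.76 with an estimated correlation), with Fdps at 1.12. The arginine and polyamine list was lower (0.0428, adjusted p = 1 with an estimated correlation), and by both counts Arg2 and Sat1 (-0.85) were lower and Srm (0.79) and Azin1 (0.74) higher. Among lists that were not called, 6 macrophage identity genes of 13 were higher and 4 lower, 7 and 4 adjusted over the list alone, with the complement gene C1qb at 1.96 and Cebpa at -1.64. Of 16 lysosome genes 3 were higher and 7 lower by both counts, with Lipa at -1.01. With limma 0 of 12 type I interferon-stimulated genes passed. All these counts stand beside 1612 of 3345 tested genes that passed in this comparison, so a list with about that share of its members called does not stand out by its count.

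The third comparison asked which genes follow the origin of the lmr segments. H2-Ea was lower with C57BL/6 segments (log2 -5.39 ± 0.19, SE, n = 8 arrays, adjusted p = 8.22e-05), where its mean of 1.83 lay far below the filter, so the true size is not measured, and the glyoxalase gene Glo1, also on chromosome 17, was lower by 2.42-fold (log2 -1.27, adjusted p = 0.00356). Also lower were Usp2 on chromosome 9 (-1.31), Gfer (-0.76) and the cholesterol transporter Abcg1 (-0.60) on chromosome 17, and Csad (-0.56). Higher with C57BL/6 segments were Ccn2 (1.85), smooth muscle actin Acta2 (1.51), the collagen chaperone Serpinh1 (1.61 and 1.38 in the 2 congenic comparisons), Col5a2 (1.34), biglycan (Bgn, 1.14), Col1a1 (1.03), Tagln on chromosome 9 (1.02) and the protease inhibitor Timp1 (0.64). Zfp758 (0.97) and Vps52 (0.78) on chromosome 17 and Nsun2 (0.76) were also higher. For 8 of the 16 called genes named by the rule, the lower side lay below the filter of log2 5, where background signal limits the size. These were H2-Ea, Gfer, Ccn2, Serpinh1, Col5a2, Tagln, Zfp758 and Vps52. For Serpinh1 (means 4.89 and 3.4) and Tagln (4.94 and 3.92) the means of both segment origins lay below it. With the mean of all probe sets Bgn, Nsun2 and Usp2 did not pass (0.57, 0.38 and -1.26), and Col1a1 stood at 0.66. The next in size did not pass: Rest at -1.12, Pla2g7 at -1.03, H2-T24 at -0.97 and Acod1 at -0.96 (-0.59 with the mean of all its probe sets). Fli1, which lies in the lmr2 region, stood at 0.55 in the BALB/c-background and -0.33 in the C57BL/6-background comparison. The first of these values was 1.82 between the uninfected arrays, among them the BALB/c array with the largest actin 3′ minus 5′ difference, and -0.72 between the infected arrays. In all 24 genes passed, 18 higher and 6 lower. The excess of higher genes shrank to 9 against 5 with quantile normalisation again and to 6 against 5 with each array shifted to the same median. It turned round with the log2 7 filter, with 2 higher and 3 lower.

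This count moved with the fit. On simulated data 14.1% of segment calls were false (32 of 227), in a fit with a strain correlation of -0.318. That share does not carry over to the 24 calls here, which are fewer than those 32 false ones. Without the strain block only H2-Ea passed, with the arrays of a strain averaged 11 genes passed, 9 of them among the 24, and with an infection-by-background term in place of the block 4 passed (H2-Ea, Glo1, Col5a2 and Acta2). Without any 1 strain the count was 1, and without the uninfected BALB/c array 1302 genes passed, a fit in which the correlation between the arrays of a strain was estimated at -0.887. Of the 24 genes 10 lay on chromosomes 9 and 17 (4 and 6), against 387 of 3340 tested genes with a known chromosome (11.6%), an odds ratio of 5.56 (95% CI 2.19 to 13.6, one-sided Fisher exact p = 0.00017). For the 50 genes of smallest p the odds ratio was 3.04 (exact p = 0.00114), and without the uninfected BALB/c array it was 1.18 (exact p = 0.0753). The 2 congenic comparisons share no array. Across genes their segment differences correlated with r = 0.788 on chromosome 17 (200 genes, rho = 0.388; without H2-Ea r = 0.498 and rho = 0.379), r = 0.327 on chromosome 9 (187 genes, rho = 0.248) and r = 0.292 on the other chromosomes (2958 genes, rho = 0.217). Among genes differing by at least 0.5 in both comparisons, the sign was shared by 12 of 13 on chromosome 17 and 5 of 5 on chromosome 9. On the other chromosomes it was shared by 45 of 48, 34 of them higher with C57BL/6 segments, so such agreement was not confined to the segment chromosomes.

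**Figure D4:**
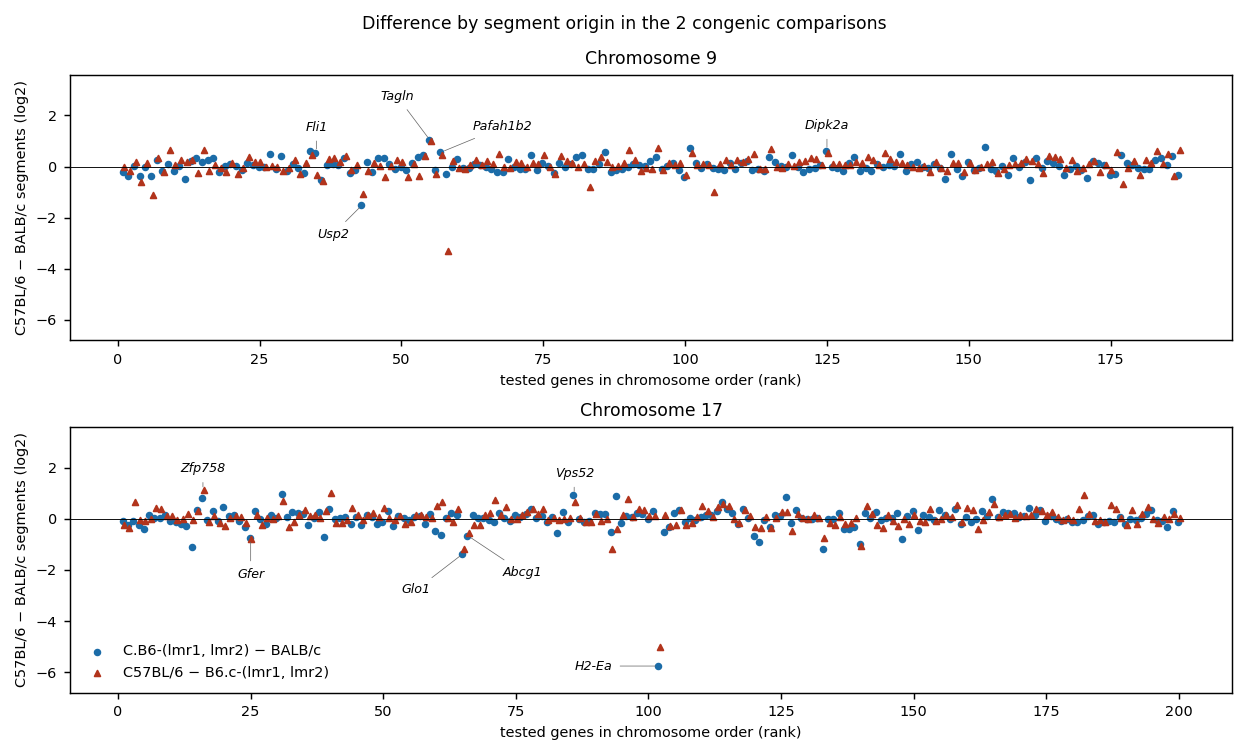
Log2 difference between C57BL/6 and BALB/c segment origin for each tested gene on chromosomes 9 and 17, in chromosome order, in the BALB/c-background (circles) and the C57BL/6-background comparison (triangles). Labels mark the called genes and Fli1. H2-Ea lies far below the rest in both comparisons, at -5.76 and -5.02, and the unlabelled triangle near -3.29 on chromosome 9 is Cadm1, which did not pass (adjusted p = 0.271).

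Markers of fibroblasts were among the lists tested for segment origin. Here too the camera version with an estimated correlation left out the strain block. Of the fibroblast list, Acta2 and Col1a1 were higher with C57BL/6 segments (2 of 4 tested genes by both counts, over all genes and adjusted over the list alone; camera adjusted p = 1.04e-04, and adjusted p = 0.943 with an estimated correlation). Of the 12 tested matrix remodelling genes 1 was higher, 2 adjusted over the list alone (median -0.02, camera adjusted p = 0.938). For the 8 called genes from Ccn2 to Timp1 above, grouped after their values were seen, the mean log2 value was 7.17 on the uninfected C57BL/6 array and 6.84 on the uninfected C.B6-(lmr1, lmr2) array, against 5.72 in uninfected B6.c-(lmr1, lmr2) and 5.05 in uninfected BALB/c. The 8 genes were picked as higher with C57BL/6 segments, so this order of the strains follows from the choice. Their mean infected minus uninfected difference was -0.45 in BALB/c, -1.29 in C.B6-(lmr1, lmr2), -1.91 in C57BL/6 and -1.28 in B6.c-(lmr1, lmr2), and 6 of the 8 genes, Serpinh1 and Bgn excepted, had a negative difference in all 4 strains. None of the 8 passed the infection test over the 4 strains, and within the C57BL/6 background 7, all but Timp1, passed, from Bgn at -0.93 to Acta2 at -3.06. The MHC list was lower with C57BL/6 segments (camera adjusted p = 4.94e-09, and adjusted p = 0.943 with an estimated correlation). Of its 12 genes 1, H2-Ea, passed, and 3 were lower adjusted over the list alone. The list had a mean of -0.58 and a median of -0.03, and it was not tested without H2-Ea. The cytokine list was lower too (0.0323, adjusted p = 0.943 with an estimated correlation), with 0 of 9 genes past the limma threshold and 2 lower adjusted over the list alone.

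**Figure D5:**
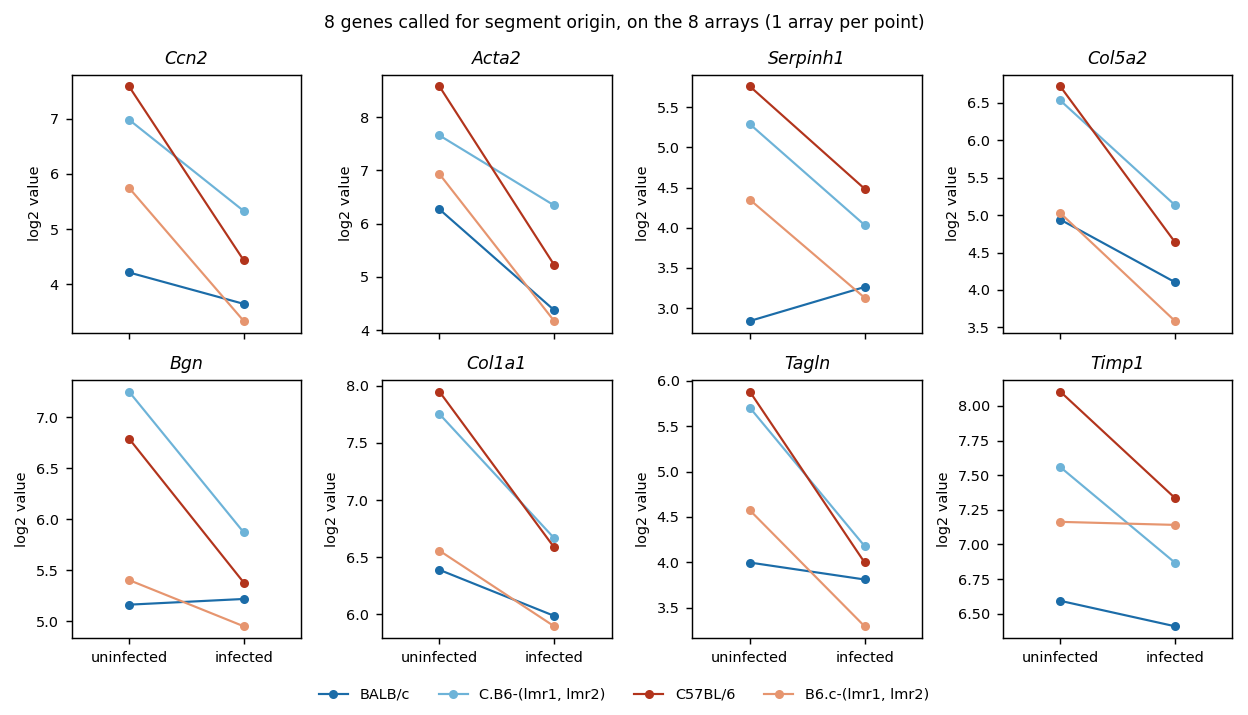
Log2 value of 8 genes called for segment origin, grouped after their values were seen, on the uninfected and the infected array of each strain, 1 array per point, with a line joining the arrays of a strain. The uninfected arrays of C57BL/6 and C.B6-(lmr1, lmr2), the strains with C57BL/6 segments, hold the highest values (means 7.17 and 6.84), which follows from how the genes were picked. Most lines slope down from uninfected to infected.

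Whether the response to the parasite depends on segment origin was tested last. The genes of smallest p were the chemokine genes Cxcl2 (difference in response, C57BL/6 minus BALB/c segments, log2 -2.00), Cxcl1 (-1.81) and Ccl3 (-1.37), with Rbm39 (-1.41, or -0.54 with the mean of all its probe sets) and the cyclin-dependent kinase Cdk1 (1.30). None passed. Limma called 0 of 3345 genes (smallest adjusted p = 0.991), and 106 had an unadjusted p under 0.05. On simulated data this test recovered 0% of differences of log2 4 and the infection-by-background test, on the same 4 differences, 56.1%. Each share comes from a single simulated draw. The balanced design gives both tests the same power, so the gap does not show a weaker test for segment origin. Genes of macrophage polarisation were set apart before the data were examined. Arg1, Nos2, Il12b and Il10 lay below the expression filter, at log2 values of at most 2.64, 1.99, 3.79 and 2.71. Tnf rose by 1.02 in the C57BL/6 background (adjusted p = 0.00698), and Tgfb1, at 0.41 there, did not pass.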

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

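The counts over other splits of the arrays were set before their results were seen, and the other tests in this part, with the criteria by which they were read, were chosen after. The criteria for exchanged labels, poor RNA, fibroblast-like cells and probe sequence, and the reading of the splits by whole strains, were also rewritten once the values were known.

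The response to the parasite differed between the backgrounds for 119 genes by the interaction test, C57BL/6 minus BALB/c background. The 5 genes of smallest p were Fpr2 (log2 6.83), Acod1 (7.74), Marco (6.76), Birc5 (-5.52) and Cp (6.10). With an intensity trend in the variance no gene passed with limma, 658 genes had an unadjusted p under 0.05, and the adjusted p of these 5 genes reached 0.305. One array stood apart from the other 3 of its background: uninfected BALB/c had a Gapdh 3′ minus 5′ log2 difference of 1.64, where the other 7 arrays lay between 0.55 and 0.95. Its gap to the nearest array was 0.939 of the range, above Dixon's 95% limit for 4 arrays, in 1 of 6 groups examined, and chance gives about 1 in 20.

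The response of the C.B6-(lmr1, lmr2) pair ran against that of the C57BL/6-background pairs (r = -0.413 and -0.406 across genes). Poor RNA on this pair stays open: its actin 3′ minus 5′ differences of 1.42 and 1.27 lay below uninfected BALB/c, by 0.668 for the higher, but above the other 5 arrays, and its Gapdh differences of 0.77 and 0.76 lay below uninfected BALB/c (1.64) and infected C57BL/6 (0.95) and above the other 4. Exchanged labels within the pair could produce such a pattern: of 20 genes changed at least 2-fold the same way in the other 3 strains, 20% (4 genes) had that sign in this pair, but this share restates the pattern, over genes that are not independent, and decides nothing. The 8 genes grouped under segment origin had a mean difference of -1.29 in this pair, the sign of the other 3 (-0.45, -1.91 and -1.28), but they were grouped after their values were seen, so the label question stays open. A strain difference in the response is also open, and the design has 1 pair of this strain to judge it by.

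Among the genes called for segment origin were 8, grouped after their values were seen, that stood higher with C57BL/6 segments, and without the strain block their adjusted p ran from 0.243 (Col5a2) to 0.857 (Tagln). A differing share of fibroblast-like cells could account for this, although the culture discarded early adherent cells to remove fibroblasts. Of the 5 other members of the fibroblast list above log2 4 on any array, 2 (Postn and Sparc) were higher by at least 0.5 in both comparisons, whereas Col1a2, Col5a1 and Fbln1, at up to 5.87, 5.70 and 4.42, were not, so the members did not move alike. A direct effect of genes in the segments remains open too: the smaller median was 0.892 of the larger, a closeness that follows from how the genes were called and decides nothing, and 1 of the 8 genes lies on chromosome 9 or 17. These explanations cannot be told apart with 1 culture per strain and infection state.

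Many genes differed between the backgrounds (1612). Sequence differences under the probes might lower values in one strain. If the probes match C57BL/6 best, most differences would be higher there, but of 232 calls of at least 2-fold 43.1% were (100 genes, exact 95% CI 36.6 to 49.7), and with arrays shifted to the same median 47.9% (CI 41.5 to 54.4), so this stays open. A labelling or hybridisation batch or RNA quality cannot be told apart from background. Spike-in means (1.15) and actin 3′ minus 5′ differences (-0.56, or -0.36 without uninfected BALB/c) separated the backgrounds with no overlap. Gapdh 3′ minus 5′ differences overlapped between them (-0.23, or -0.01 without uninfected BALB/c), so the controls of RNA quality differ on this. A genetic difference, which the design names, stays open.

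Among 35 splits of the 8 arrays, 1, the real one, gave 1612 genes or more for the background, with 258 the highest of the others. For segment origin 3 of 35 gave 24 genes or more. The other 2 were the split by background (1186 genes) and the split by infection and background together (328), which point to a structure of the samples. Only 3 of the 35 splits keep the arrays of each strain together, as the real ones do, too few for a share under 0.05. Among these 3 the highest other count was 1 for the background and 1186 for segment origin. For infection the real count was 0, which all 32 splits had to reach, so this count of splits says nothing about chance. The highest of the others was 599, for splits that follow infection within the C57BL/6 background.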

How the results depend on the processing

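The fits within each background, without the uninfected BALB/c array, with an infection-by-background term and of the interactions without a strain were chosen after the data were examined. Of 90 alternatives for counts and tests, 60 stayed within 1.5 times or on the same side of the threshold. These 60 include every alternative of infection, infection by segment and infection within the BALB/c background. There a count of 0 stayed at 0, which says nothing about how firm a call is. Infection, infection by segment and infection within the BALB/c background stayed at 0 with limma in every fit run, with 55 to 661, 12 to 397 and 37 to 219 genes at an unadjusted p under 0.05. Without a filter the counts were 12 for segment, 44 for infection by background and 1314 for infection within the C57BL/6 background, and with the log2 7 filter 5 for segment, 911 for background and 379 for the C57BL/6 background. Those filters change the number of genes tested. For segment, quantile normalisation gave 14 and a shift to the same median 11, and the share higher went from 75% to 64.3% and 54.5%. The median shift moved the median of all genes by 0.105 within the C57BL/6 background, where the share higher went from 38% to 50.9%, and by 0.109 for infection by background. Without the strain block background gave 667 and segment 1, with averaged arrays segment gave 11, and with the added term 4. An intensity trend took infection by background to 0 (658 unadjusted), and dropping its segment term gave 293, or 21 to 381 with each strain also left out and the lone pair assumed to vary like the others. Leaving out each strain gave 771 to 1103 for background, 1 to 1 for segment, 8 to 9 lists under infection and 16 to 194 consistent responders. Without the uninfected BALB/c array segment gave 1302 and its chromosome odds ratio was 1.18, over 1299 called genes with a known chromosome. With an estimated correlation 0 lists passed under infection, from 10. With the mean of all probe sets 100 named values kept their sign and side of the threshold, and 3 calls ended: Bgn 0.57, Nsun2 0.38 and Usp2 -1.26. The size moved by over 1.5 times for 15 named values, the most for Pdxdc1 (-0.51). Except for the number of genes or arrays, the cause was not tested. Without a strain the interactions could not be fitted with both terms. Leaving out a strain was not run for the fits within a background, and for background and segment it kept the correlation of the 8 arrays fixed. Signal over background limits Arg1, Nos2, Il12b and Il10, which lay under the filter.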

Other observations

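The groupings and genes in this part were chosen after the data were examined, and none of these differences was tested unless an adjusted p is given.

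The levels of genes that responded in the C57BL/6 background follow for all arrays. These genes were picked for their difference in that background, so its arrays hold the extremes by construction. For the 131 genes at least 2-fold higher in both C57BL/6-background pairs, the median log2 value was 5.74 on the uninfected and 8.48 on the infected C57BL/6 array, and 5.67 and 8.36 in B6.c-(lmr1, lmr2). It was 6.87 uninfected and 7.06 infected in BALB/c, and 7.11 and 6.55 in C.B6-(lmr1, lmr2). For the 191 genes at least 2-fold lower in both pairs, the medians were 7.16 and 5.15 in C57BL/6, 6.99 and 4.85 in B6.c-(lmr1, lmr2), 6.25 and 5.86 in BALB/c, and 6.04 and 6.44 in C.B6-(lmr1, lmr2). In BALB/c 53.4% of the 131 genes were higher and 67% of the 191 lower on the infected array, and in C.B6-(lmr1, lmr2) 16% and 24.1%.

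Single genes had their own patterns. The metallothioneins Mt1 and Mt2, which bind zinc and copper, had infected minus uninfected log2 differences of 1.34 and 1.82 in C.B6-(lmr1, lmr2), the pair whose labels are in doubt, 0.24 and 0.08 in BALB/c, -1.89 and -0.90 in C57BL/6 and -1.88 and -0.50 in B6.c-(lmr1, lmr2). The difference in response between backgrounds was -1.65 for Mt2, which did not pass (adjusted p = 0.249), and passed for Mt1 (-2.67, adjusted p = 0.0478 with limma), a test in which no gene passed with an intensity trend (smallest adjusted p = 0.0689, 658 genes at an unadjusted p under 0.05). Fli1, a transcription factor gene in the lmr2 region, stood at log2 4.64 on the uninfected BALB/c array, the one with the largest actin and Gapdh 3′ minus 5′ differences, and at up to 7.21 on the other 7, all of them higher. Cadm1, a cell adhesion gene on chromosome 9, had a segment difference of -3.29 in the C57BL/6 background and -0.29 in the BALB/c background.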
